A study of Homo sapiens with 6 samples.

How the data were processed

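RNA expression was measured on Affymetrix HG U133 Plus 2 arrays in 6 samples of cells labelled LoVo, 3 transfected with ArhGAP30 and 3 with the empty vector, 48 hours after treatment. Groups and replicate numbers were taken from the sample labels, which do not say whether the transfection was transient or stable. The labels do not say whether replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

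The values were probe set intensities on a linear scale as deposited, 1 value per probe set and array. The submitters' processing notes name MAS5 and RMA, with no role, order or version given in the sources used here. Each array had a 2% trimmed mean signal of 500.1, the kind of global scaling that MAS5 applies, and the values were not on the log2 scale that RMA gives. No detection calls were used here, and scanner files were not used here. Such scaling sets 1 factor per array and leaves differences in the shape of the signal distribution between arrays in place, which can shift groups of very bright genes together. The number of arrays limits the precision of every comparison.

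Of 54675 probe sets, 62 were array controls and were left out. The annotation paired 41091 of the others with 1 gene symbol, 1801 with several and 11721 with none. Symbols were updated through Entrez gene numbers to those of the GRCh38.p14 gene annotation, which was used only for names and for which genes neighbour each other. Only probe sets with 1 symbol were named. They covered 19775 genes, and each gene was represented by its probe set with the highest mean log2 value over the 6 arrays. Signals were analysed as log2(signal + 16) with no further scaling. The pseudocount of 16 means that fold changes understate the change of dim genes. Genes whose probe set lay at or below the 40th percentile of all non-control probe sets, a signal of about 29.2, were left out, which left 14003 genes.

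ArhGAP30 was compared with vector control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, without a replicate block. The test was two-sided, p-values were adjusted by Benjamini-Hochberg, and genes with adjusted p under 0.05 were called. A second count took called genes with at least 2-fold change. ARHGAP30 was tested in a fit without the filter on dim probe sets and without the pseudocount. Its probe sets were also tested by an exact permutation test of these log2 values. Means are given with the SD over 3 arrays per group, and fold changes with the standard error or the 95% confidence interval of the limma fit.

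Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over 34 lists. They were p53 targets, p53 acetylation and stability machinery, apoptosis regulators, G2/M and G1/S cell cycle genes, actin and focal adhesion genes, SRF, YAP/TAZ and Wnt targets, epithelial junction, mesenchymal and colon epithelial genes, interferon, NF-kappaB, immediate early, unfolded protein and integrated stress response, heat shock, hypoxia and glycolysis, cholesterol, oxidative phosphorylation, ribosomal protein, histone, autophagy and lysosome, DNA repair and housekeeping genes. Further lists held markers of lymphoid cells, myeloid cells, fibroblasts and muscle, endothelium, and neurons and glia, and a reference list of tissue-restricted genes. The other 3 lists are not reported here. The genes named in the text were ARHGAP30 and, in each direction, the 12 called genes with the largest log2 fold change whose groups did not overlap and whose higher mean was above the median probe set (signal 47.6). Within each list up to 4 called members were named or, where none was called, the 2 brightest, and a list could also be given as counts alone. The groups, tests, gene lists, naming rule and other settings were fixed before the data were examined. The pseudocount departed from them in the fit for ARHGAP30 and in the settings that changed the filter.

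Other settings tried were quantile normalization and median centring between arrays, pseudocounts of 1 and 64, a floor at the 20th percentile, no filter or one at the 60th percentile on dim probe sets, the mean of a gene's probe sets, every probe set tested alone, leaving out cross-hybridising probe sets, eBayes without the trend or with robust fitting, array weights, the replicate number as a block, and leaving out each array. Both settings that changed the filter also changed the pseudocount, to none without the filter and to 60 with the stricter one. They therefore do not show the effect of the filter alone. For gene lists, camera with an estimated correlation and fry were also run. Fry's directional test asks for a shift to one side and its mixed test for change in either direction, and both compare a list with no other genes. The search along chromosomes was added after the data had been seen. It took the median log2 fold change in windows of 50 neighbouring genes against 1000 permutations of the gene order.

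The limma step was tested on simulated data with 14003 genes and 200 changed genes per run. It recovered 48.8% of genes changed 1.5-fold, 65.2% at 2-fold, 84.8% at 4-fold and 91.6% at 8-fold, with 5.35% of calls false. A simulated list shifted by 0.3 was called in 10 of 10 runs, and 2 lists without a shift of their own were called over those runs. The simulated genes varied independently, so these runs do not show how often lists of correlated genes are called without a shift. In simulated data without any shift, the largest window median (0.147) just passed the bound of the permuted gene order (0.145), so a window near the bound says little. Figures were drawn with matplotlib 3.10.9.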

Results

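Gene expression was profiled in cells labelled LoVo, a human colorectal carcinoma line, transfected with ArhGAP30, a GTPase-activating protein, or with the empty vector pcDNA3.1, 48 hours after treatment. Each group held 3 arrays. Median signals of the arrays ran from 54.3 to 63.4. Pearson's r of log2 values across genes, which are not independent replicates, was 0.978 to 0.979 within vector control, 0.972 to 0.980 within ArhGAP30 and 0.971 to 0.978 between the groups. ArhGAP30 replicate 2 stood somewhat apart, with an actin 3'/5' signal ratio of 9.76 against 7.13 to 8.52 on the other arrays. All values below are mean signal ± SD with n = 3 arrays per group unless stated, with vector control first, and adjusted p-values are from limma. Members of gene lists are given as group means.

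The level of the transfected gene was examined first. ARHGAP30 had 3 probe sets, all dim. Probe set 241346_at read 14.2 ± 3.18 in vector control and 56.5 ± 13.5 in ArhGAP30, and its 3 ArhGAP30 arrays all lay above its 3 control arrays. The log2 fold change of 1.99 (SE 0.75) did not pass among all genes (adjusted p = 0.441). It was taken without the pseudocount, so it is not on the scale of the other genes' fold changes. The exact permutation test of its log2 values gave p = 0.1, two-sided, the smallest that 3 against 3 arrays allow. Probe set 226219_at read 9.69 ± 5.33 and 8.65 ± 5.34, and 243433_at read 25.6 ± 29.6 and 18.9 ± 19.9, differences smaller than the spread between arrays (exact p = 0.8 and p = 0.7). Whether any of these probe sets lies within the transfected sequence is not given in the sources used here, so a flat probe set checks nothing. With the pseudocount of 16 used for the other genes, ARHGAP30 was not called either.

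The comparison of ArhGAP30 with vector control asked which genes differed between the groups. Higher expression of the transfected gene was not established above, and the cells of the groups may differ in other ways. The differences below are therefore not assigned to ArhGAP30. PHGDH, the first enzyme of serine biosynthesis, rose from 28.1 ± 21.9 to 698 ± 81.3. KCNJ15, an inward-rectifier potassium channel, fell from 777 ± 33.1 to 55.6 ± 34.6. In all, 160 of 14003 genes passed the threshold, 113 higher and 47 lower in ArhGAP30, and 42 of them changed at least 2-fold, 21 in each direction. The groups did not overlap in any of the 160, nor in 2384 of all genes, 17.0% of those tested against 10% by chance. The median log2 fold change of all tested genes was -0.01.

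Among the genes higher in ArhGAP30, PHGDH rose by 4.16 on the log2 scale (SE 0.35, adjusted p = 5.09e-05) and read under the filter on dim probe sets in vector control, as did HDX and EFNA3. The size of the PHGDH change depended on the pseudocount, with log2 fold changes of 5.05 at 1 and 3.07 at 64. IL13RA2, an interleukin receptor subunit, rose from 1213 ± 41.2 to 3371 ± 497 (log2 fold change 1.45, SE 0.10, adjusted p = 1.39e-05). IGFBP4, which binds insulin-like growth factors, rose from 609 ± 16.5 to 1677 ± 134 (log2 fold change 1.44, adjusted p = 1.28e-05). AGMAT, which encodes agmatinase, rose from 204 ± 23.4 to 720 ± 61.3. Its other probe sets above the filter gave log2 fold changes of 0.91 and 0.02. MCAM, a cell adhesion molecule, rose from 208 ± 91.2 to 764 ± 61.1 on a probe set that can cross-hybridise, while its other probe set changed by 0.18 (log2). HDX, a homeobox gene, rose from 3.38 ± 2.60 to 117 ± 46.0. The long non-coding RNAs SLC16A1-AS1, LINC01029 and TMEM132D-AS1 had log2 fold changes of 2.27, 2.11 and 1.37. A second probe set above the filter gave -0.08 for SLC16A1-AS1 and 2.43 for TMEM132D-AS1. EFNA3, an ephrin-A ligand, rose from 24.4 ± 7.28 to 125 ± 24.9, DMKN, which encodes dermokine, from 51.9 ± 19.9 to 208 ± 16.1, and SSX1, a cancer-testis antigen, from 62.6 ± 24.2 to 198 ± 22.2. The probe set of SSX1 can cross-hybridise too, and its other probe set, under the filter, gave 0.34 (log2). With probe sets averaged, SLC16A1-AS1, AGMAT and SSX1 were not called (log2 fold changes 0.72, 0.89 and 0.91, adjusted p = 0.576, 0.0918 and 0.513).

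Among the genes lower in ArhGAP30, KCNJ15 had a log2 fold change of -3.62 (SE 0.33, adjusted p = 0.000128), while its 4 other probe sets above the filter fell less (log2 fold changes -1.16 to -1.55), and the mean of its probe sets gave -1.82. SPOCK1, a secreted proteoglycan, fell from 2284 ± 187 to 676 ± 9.11 (log2 fold change -1.73, SE 0.10, adjusted p = 2.94e-06). UCA1, a long non-coding RNA, fell from 1442 ± 84.9 to 419 ± 45.2. MAGEB2, a cancer-testis antigen, fell from 1381 ± 66.5 to 153 ± 50.7 (log2 fold change -3.09), and PAGE5, another, from 146 ± 5.26 to 25.4 ± 28.3. DMRT1, a transcription factor of the gonad, fell from 234 ± 33.2 to 17.9 ± 23.3. CDH18, a cadherin, fell from 441 ± 52.0 to 51.3 ± 17.1. PWWP3B fell from 519 ± 25.9 to 74.4 ± 19.5, and PAEP, which encodes glycodelin, from 378 ± 26.8 to 99.6 ± 7.81. ZG16B, HLA-DPA1, an MHC class II chain, and the long non-coding RNA LINC03026 had log2 fold changes of -2.23, -1.90 and -1.76. The other probe set of HLA-DPA1 above the filter gave -0.77, and with its probe sets averaged the gene was not called (log2 fold change -1.07, adjusted p = 0.326). ZG16B and PAGE5, with 1 probe set each, were not called in that setting either.

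**Figure D1:**
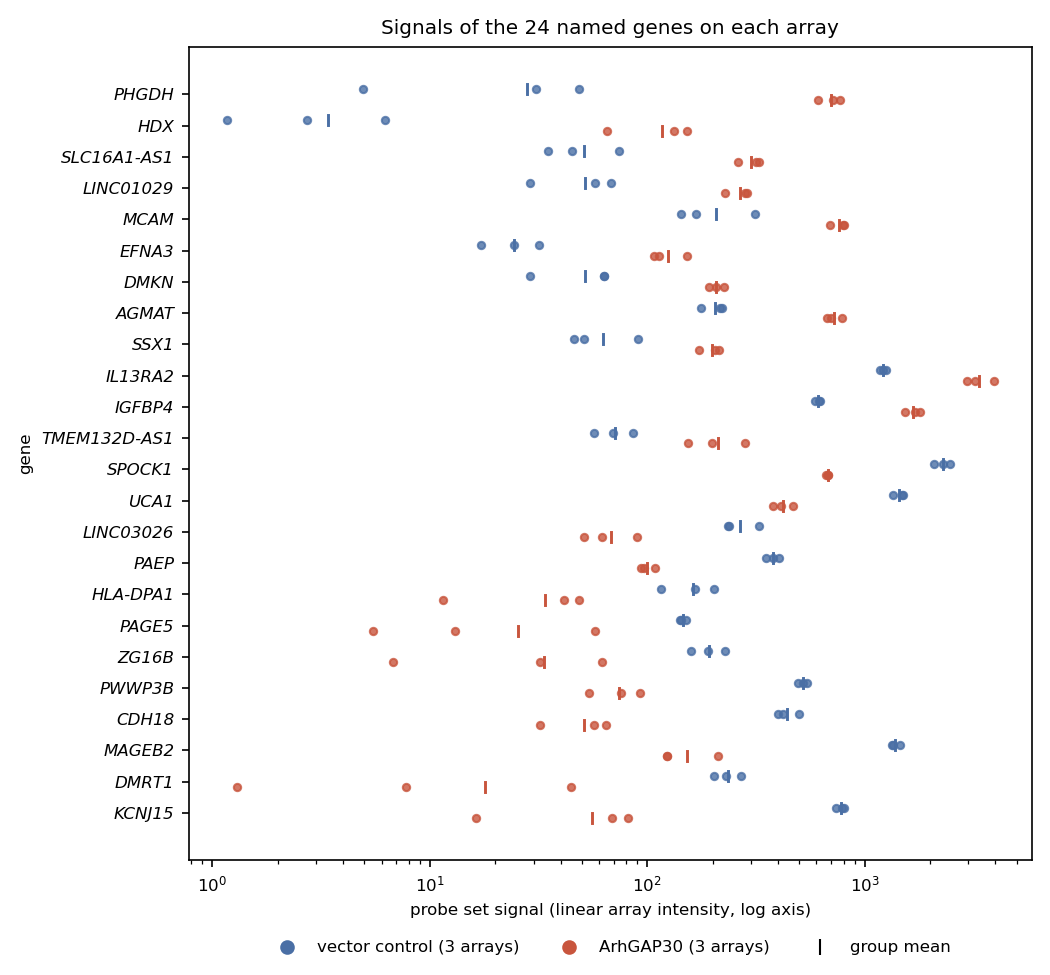
Probe set signal (horizontal, log axis) of the 24 named genes on each array, with points for single arrays and a bar for the mean of each group of 3. No gene has overlapping groups; IL13RA2 reads 1213 on average in vector control and 3371 in ArhGAP30, and SPOCK1 reads 2284 and 676.

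The number of called genes changed when 1 array was left out: it was 76, 38 and 42 without vector control replicates 1, 2 and 3, and 104, 267 and 78 without ArhGAP30 replicates 1, 2 and 3. Fewer arrays also give the test less power, so a lower count does not single out the array left out. The number of called genes was 59 when a gene's probe sets were averaged, 309 with array weights and 11 without the intensity trend in eBayes, while CDH18, IGFBP4, IL13RA2, MAGEB2, PAEP, PWWP3B, SPOCK1 and UCA1 passed in every setting fixed in advance.

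The called genes were unevenly placed along the chromosomes. Chromosome 1 held 9.96% of the 13966 tested genes with a place in the gene order and 60 of the 160 called genes, 59 of them higher in ArhGAP30. In windows of 50 neighbouring genes, the largest median log2 fold change was 0.45, against at most 0.20 in 1000 permutations of the gene order. Of 5 stretches past that bound, the longest ran on chromosome 1 from DNASE2B to RBM8A, with 163 of 190 genes higher, a median log2 fold change of 0.27 and 38 called genes, all higher. The stretch from IFT25 to ODF2L, which shares 15 genes with it, held 105 genes, with a median of 0.22 and 14 called genes, all higher. Stretches on chromosome 5 from PLEKHG4B to ADAMTS12 (70 genes, median 0.25) and chromosome 7 from PRSS2 to NOM1 (75 genes, median 0.18) were also higher. One on chromosome X from TCEAL4 to ZCCHC12 was lower (50 genes, median -0.21), only just past the bound, and its median was -0.14 without ArhGAP30 replicate 2. PHGDH and SLC16A1-AS1 lay in the chromosome 1 stretches, CDH18 in that of chromosome 5, and IL13RA2 and PWWP3B in that of chromosome X. Outside the 5 stretches, 92 genes were called, 51 higher and 41 lower.

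**Figure D2:**
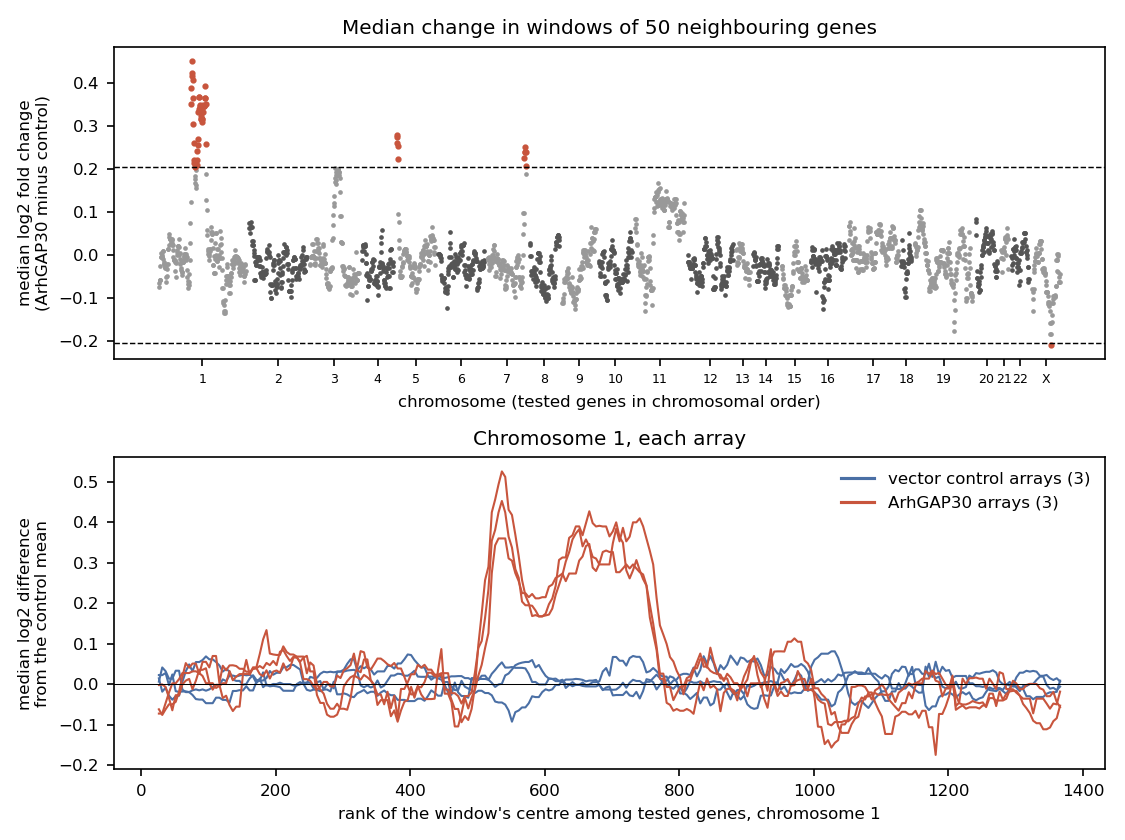
Top: median log2 fold change (vertical, ArhGAP30 minus vector control) in windows of 50 neighbouring genes in chromosomal order, with the windows past the bound of 1000 permutations (dashed, 0.20) in red. Bottom: the same windows on chromosome 1 for each array as log2 difference from the control mean; the 3 ArhGAP30 arrays lie above the 3 control arrays over the windows that reach 0.45.

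ArhGAP30 has been studied for its link to p53, so p53 target genes were examined as a group. Of 43 tested, GADD45A, a growth arrest gene, was called, 1 over all genes and 1 adjusted over the list alone. GADD45A rose from 1593 to 2580 (log2 fold change 0.69, SE 0.08, adjusted p = 0.00144) and lies in the chromosome 1 stretch from IFT25 to ODF2L. The list's median log2 fold change was -0.05, with 17 of 43 genes higher, and camera found no shift (adjusted p = 0.998). For 39 of the 43 genes the 95% interval of the log2 fold change lay within 1 of 0, and for 32 within 0.58 of 0, or 1.5-fold. CDKN1A, a cell cycle inhibitor chosen with the next genes after the values were seen, read 979 ± 63.0 and 1126 ± 50.5, with an interval of -0.01 to 0.41. MDM2 read 2017 ± 63.2 and 1824 ± 96.2, and BAX read 384 ± 134 and 337 ± 182. None of the 28 genes of p53 acetylation and stability passed in limma (5 at unadjusted p under 0.05). EP300, an acetyltransferase of that list also chosen after its values were seen, read 1302 ± 215 and 938 ± 21.7 (adjusted p = 0.111). Among 30 other apoptosis regulators, BCL2A1, an anti-apoptotic family member, rose from 192 to 455 (adjusted p = 0.0113), 1 call over all genes and 2 adjusted over the list alone.

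Cytoskeletal genes and the targets of SRF, YAP/TAZ and Wnt showed few calls. CNN3, an actin-binding calponin, rose from 9355 to 13111 among 20 SRF targets, and F3, the tissue factor gene, from 13145 to 18592 among 22 YAP/TAZ targets, each the 1 call of its list over all genes and the 1 adjusted over the list alone. CNN3 and F3 lie in the chromosome 1 stretch from DNASE2B to RBM8A. Of 38 actin and focal adhesion genes, ITGA6, an integrin chain, fell from 5250 to 2916 (adjusted p = 0.0116), with 2 genes adjusted over the list alone. No Wnt target passed among 16 over all genes (4 at unadjusted p under 0.05), and 2 passed adjusted over the list alone. At unadjusted p under 0.05 there were 7 of 22 YAP/TAZ targets, 7 of 38 actin and focal adhesion genes and 3 of 20 SRF targets. The YAP/TAZ mean lay at 0.06, 0.10 and 0.15 on the ArhGAP30 arrays and between -0.05 and 0.05 on the control arrays. Camera called none of these lists (adjusted p = 0.216 for YAP/TAZ), nor did fry's directional test (adjusted p = 0.105 for YAP/TAZ). Fry's mixed test called the YAP/TAZ list alone of these (adjusted p = 0.000999).

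Stress and metabolic lists held further calls. In the unfolded protein and integrated stress response list 3 of 32 genes were called over all genes and 5 adjusted over the list alone, all higher. Besides PHGDH these were TRIB3, a pseudokinase gene, from 488 to 881 (adjusted p = 0.00434), and ASNS, the asparagine synthetase gene, from 1858 to 2492 (adjusted p = 0.0382). The list did not pass in camera (adjusted p = 0.213). In oxidative phosphorylation 3 of 32 genes were called, and the same number adjusted over the list alone. ATP5PB rose from 26200 to 35458, NDUFV1 from 2393 to 3149 and SDHA from 2090 to 2964, with camera adjusted p = 0.0588 for the list. ATP5PB and SDHA lie in the stretches of chromosomes 1 and 5. Housekeeping genes had 1 call in 16, SDHA again, and 1 adjusted over the list alone. DUSP1, a phosphatase gene, rose from 2050 to 3033 among 27 immediate early genes (1 over all genes, 3 adjusted over the list alone). CTSL, which encodes cathepsin L, fell from 9430 to 6823 among 28 autophagy and lysosome genes (1 over all genes, 1 adjusted over the list alone).

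No gene was called by limma in the lists for G2/M (0 of 36), G1/S (0 of 38), DNA repair (0 of 23), heat shock (0 of 16), hypoxia and glycolysis (0 of 34), cholesterol (0 of 18), interferon (0 of 29), NF-kappaB (0 of 20) and histones (0 of 9). At unadjusted p under 0.05 these held 2, 3, 0, 0, 3, 1, 4, 2 and 0 genes. Adjusted over the list alone, 1 NF-kappaB gene passed and none in the other 8. UBE2C and PTTG1 of the G2/M list read 14803 and 15777, and 15156 and 15305. RRM2 and TYMS of the G1/S list read 19023 and 18647, and 14146 and 14608.

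Camera called 2 of the 34 lists. Ribosomal protein genes had a median log2 fold change of 0.12, with 30 of 31 genes higher (adjusted p = 1.16e-05) and none called singly in limma (5 at unadjusted p under 0.05, 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.999, and after quantile normalization the list's median was -0.00 (adjusted p = 0.955). Endothelial markers, 4 tested genes, had a median of 0.58 (adjusted p = 0.0077), and the adjusted p was 0.999 with an estimated correlation. ROBO4 rose from 126 to 270, while PECAM1 read 357 and 482, ESAM 196 and 342, and EMCN 42.3 and 43.8. Of these 1 was called over all genes and 3 adjusted over the list alone. In the setting without the filter on dim probe sets, which also dropped the pseudocount, the endothelial list's median was -0.54. No gene was called over all genes among markers of lymphoid cells (8 tested, 1 at unadjusted p under 0.05), myeloid cells (6, 1), fibroblasts and muscle (8, 1) and neurons and glia (8, 0), or among tissue-restricted genes (12, 1). Adjusted over the list alone, 1 myeloid marker passed. The median, the mean and the camera direction did not share a sign in 11 lists, none of them called. In the lists described, genes past the threshold only when adjusted over the list alone, named after their values were seen, were BID, PFN1, SOX9, TNFRSF19, LAMB3, AGR2, IL1B, JUN, JUND, CARS1, PDIA4, LAPTM5, ESAM and PECAM1. IL1B among them fell from 749 to 311 (adjusted p = 0.0606 over all genes).

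**Figure D3:**
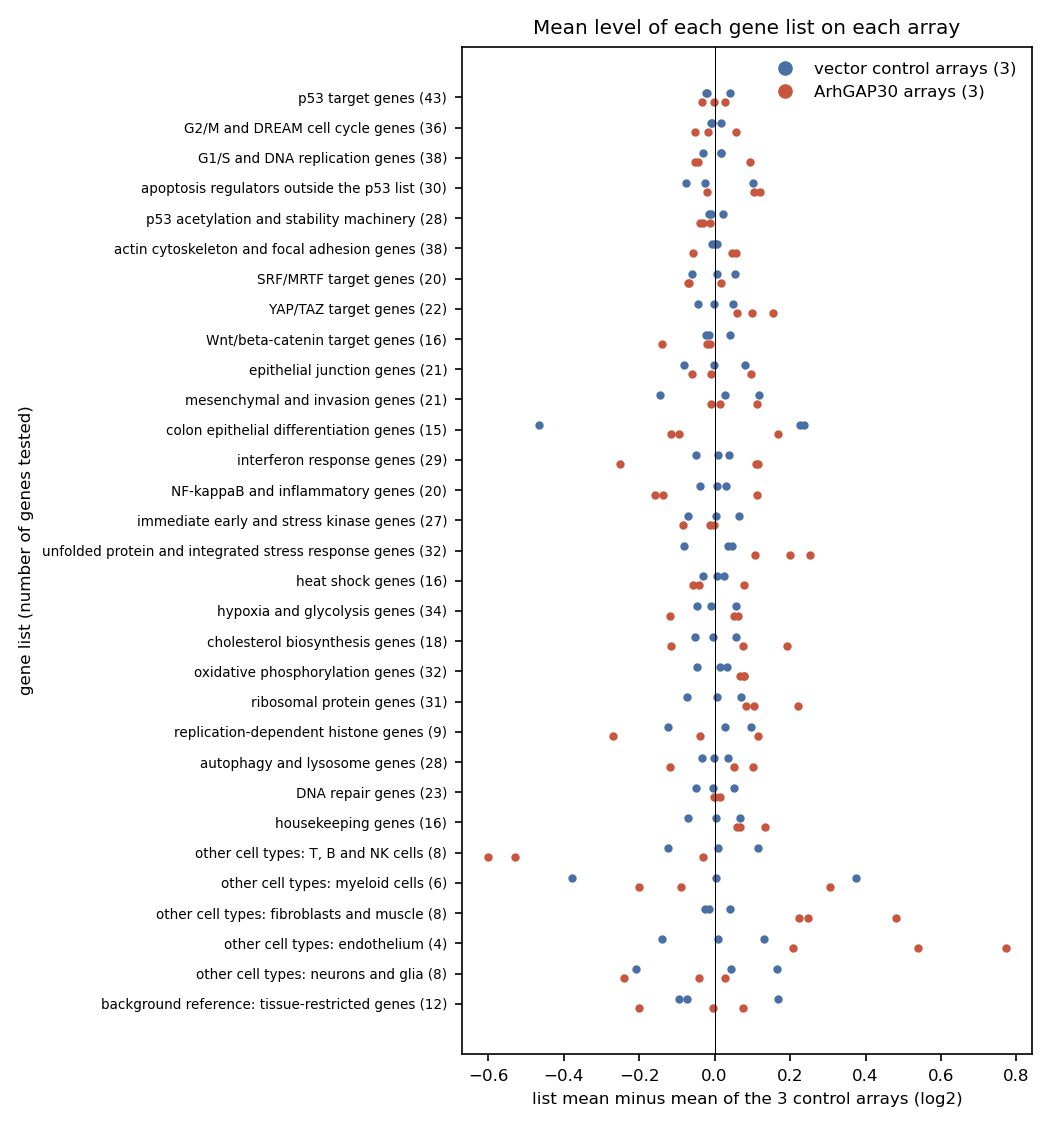
Mean log2 level of each gene list described on each array relative to the mean of the 3 control arrays (horizontal, log2), with the number of genes tested in brackets. Ribosomal protein genes lie at 0.08, 0.22 and 0.10 on the ArhGAP30 arrays and between -0.07 and 0.07 on the control arrays.

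Epithelial and mesenchymal genes were examined for their levels as well as their changes. No epithelial junction gene was called among 21 in limma (3 at unadjusted p under 0.05, 0 adjusted over the list alone). SNAI2, a transcription factor of mesenchymal cells, fell from 4389 to 3306 among 21 mesenchymal genes (1 over all genes, 2 adjusted over the list alone). CA2, a carbonic anhydrase gene, fell from 253 to 118 among 15 tested colon epithelial genes (1 over all genes, 2 adjusted over the list alone). Over all 31 colon epithelial genes with a probe set, the median signal over the 6 arrays was 30.2, against 30.7 for 31 tissue-restricted reference genes, and 27 of the 31 read under 100 on average. CDX2, CDH17, KRT20 and LGALS4 averaged 15.0, 19.6, 8.97 and 53.2, while KLF4 averaged 3579 and AGR2 592. Of the epithelial junction genes, CDH1 and EPCAM averaged 18.3 and 36.1, against 19177 for KRT18 and 4052 for DSP. Mesenchymal genes had a median of 480, with VIM, which encodes vimentin, at 55599. CDH2, TWIST1 and SNAI1 of that list averaged 26.4, 11.8 and 35.2, and 8 of its 26 genes with a probe set read under 100. The colon list's median ran from 11.9 to 42.4 over the 6 arrays and that of the mesenchymal list from 459 to 535.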

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

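Probe sets outside the comparison of named genes also carried a difference between the groups. Of 6255 probe sets above the filter on dim probe sets that are paired with no single gene, 21 passed the threshold in limma, and all 21 were higher in ArhGAP30. Of these, 8 are annotated to several genes and 13 have no gene symbol. Of the 13, the largest log2 fold changes were those of 2 probe sets. Probe set 213711_at read 5185 ± 420 in vector control and 8976 ± 1200 in ArhGAP30 (n = 3 each, log2 fold change 0.78, adjusted p = 0.0027). Probe set 224818_at read 658 ± 111 and 1146 ± 168 (log2 fold change 0.79, adjusted p = 0.0251). No explanation was tested for them.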

How the results depend on the processing

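With 3 arrays per group, leaving out an array moved the counts, and it also lowers the power of the test. Leaving out 1 array at a time gave 38 to 267 called genes and 20 to 49 with at least 2-fold change. The lowest came without vector control replicate 2 (38 of 38 shared with the 160), the highest without ArhGAP30 replicate 2 (150 shared). Without vector control replicates 1 and 3 the 2-fold count was 27 and 23. Averaging probe sets gave 59 called genes and 24 at 2-fold, eBayes without trend 11 and 11, and array weights 309, which held all 160. Of the 11, 3 were higher, 27.3% against 70.6% of the 160. Without genes of the chromosomal stretches, an alternative added after the data were seen, 92 remained. The numbers of called gene lists were 1 after quantile normalization, 0 with an estimated correlation and 0 with fry's directional test. The number was also 1 without the filter on dim probe sets, a setting that dropped the pseudocount too. The numbers were 3 with pseudocount 1, 3 each without vector control replicates 1 and 3 and ArhGAP30 replicates 1 and 2, and 2 in the other settings in which lists were tested. Every probe set tested alone was run for genes only. Fry's mixed test, of change in either direction, called 11. The ribosomal median was 0.12 as reported, and -0.0046 after quantile normalization. Its adjusted p was 0.999 with the estimated correlation and 0.545 with fry's directional test, where the median of 0.124 is the same by construction. The endothelial median of 0.578 likewise had adjusted p of 0.999 and 0.105. It was -0.544 (camera adjusted p = 0.193) without the filter. There dimmer genes entered and the pseudocount was dropped as well, so these changes cannot be told apart. The causes of the other shifts were not tested. The p53 list passed in no camera setting and not in fry's directional test, but did in the mixed test (adjusted p = 1.31e-05). ARHGAP30 passed in no setting, with log2 fold changes from 0.48 (mean of its probe sets) to 2.20. These values do not share a scale, since they were taken without a pseudocount except in the settings that set it to 1 or 64. The log2 fold change was 1.99 without a pseudocount, 1.91 with pseudocount 1 and 0.62 with pseudocount 64. In the fit of the other genes, with the pseudocount of 16, ARHGAP30 was not among the 160 called genes. Over 24 named genes, 291 of 329 values outside the single-array settings kept direction and threshold, 38 lost the threshold and 0 reversed, and with 1 array left out 104 of 141 kept both, 37 lost the threshold and 0 reversed. EFNA3, HLA-DPA1 and PAGE5 lost it in 10 settings each, TMEM132D-AS1 in 9, SSX1 and ZG16B in 7. With the replicate block 136 genes were called, 125 of them shared with the 160. Deviations of same-numbered arrays correlated at 0.0078, 0.0069 and 0.016, so the numbers were not taken as pairs. Although 6 of 6 arrays correlated best with their own number in the other group, the deviations were taken from group means. The 6 outcomes therefore depend on each other and are at most a weak hint of pairing. Low signal limits PHGDH, HDX, EFNA3, DMRT1, PAGE5 and ARHGAP30, whose lower group reads under the filter's 29.2.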

Other observations

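Families of genes outside the fixed lists were looked at because members stood among the called genes, so their p-values are too small and describe these arrays only. Insulin-like growth factor binding proteins had 2 of 6 tested genes called (Fisher's exact test two-sided, adjusted p = 0.00472 over 5 families). IGFBP1 rose from 438 ± 71.9 to 756 ± 106 (n = 3 each, log2 fold change 0.77), and IGFBP4 rose as described. Cancer-testis antigens had 3 of 19 called, MAGEB2 and PAGE5 lower and SSX1 higher (Fisher's exact test, adjusted p = 0.00472). Cytosolic aminoacyl-tRNA synthetases had 1 of 15 called, SARS1, from 7641 ± 443 to 11820 ± 78.5, which lies in the chromosome 1 stretch from DNASE2B to RBM8A. Metallothioneins had 1 of 7 called and HLA class II genes 1 of 9. Of 483 tested genes on chromosome X, 13 were called, 3 higher and 10 lower.

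The tests for copy number and for splits of the arrays on chromosome 1, and both tests on the colon genes, were chosen after the result was seen. The others were set down before their results were seen. Genes of chromosome 1 from DNASE2B to RBM8A were higher together in ArhGAP30. A scaling artefact tied to signal and a single array are argued against, since the median log2 fold change of the stretch after quantile normalization was 0.272 and the lowest ArhGAP30 array lay 0.256 above the highest control array. A difference in copy number between the cells of the groups may account for it: split by mean level into 3 equal parts, the stretch's genes had medians of at least 0.11, and 14.2% of its genes were lower, which passes narrowly the bounds chosen (above 0.1, under 20%). The stretch was chosen for high window medians in the same data, which makes both bounds easier to pass. The other stretches that were higher missed 1 or both bounds, with lowest parts of -0.06 (IFT25 to ODF2L), 0.10 (chromosome 5) and 0.06 (chromosome 7) and 22.9%, 22.9% and 30.7% of genes lower. In each stretch that was higher, the lowest part was that of the dimmest genes, whose changes the pseudocount understates. The middle and brightest parts of these other stretches had medians of 0.28 and 0.27, 0.27 and 0.28, and 0.24 and 0.18. The bounds therefore cannot decide on copy number there. Whether a difference in copy number or an effect of ArhGAP30 spread over neighbours raised the stretch from DNASE2B to RBM8A stays open. The 10 splits of the arrays are too few for a share under 0.05 (over all windows the largest median of the real split, in the stretch from IFT25 to ODF2L, was 0.450, and the highest other 0.242, with 1 split as large, against at most 0.250 in the chromosome 7 stretch and -0.208 in that of chromosome X).

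Ribosomal protein genes were higher together in ArhGAP30. Scaling between arrays that depends on signal could produce this: among 10000 random lists matched on mean level, whose median was 0.10, the list's median lay at the 97.1 percentile, and after quantile normalization its median was -0.0046. ArhGAP30 replicate 2 had the highest mean. The lower of replicates 1 and 3 lay 0.0141 above the highest control array, which leaves open whether replicate 2 alone carried the shift. An effect of ArhGAP30 was not separated from these.

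Genes of the colon epithelium read about as low as tissue-restricted genes on average over the 6 arrays, while VIM, KRT8, KRT18 and KRT19 were bright. One hypothesis is that the arrays hold cells other than colon epithelial cells. The mesenchymal list's median was at least 10.8 times that of the colon list on every array, but signals of different probe sets share no scale and the colon list reads near background, so this decides nothing. A mixture of colon cells with another type is a second, and the colon list's median reached 2.64 times that of the tissue-restricted list on 1 array and 0.75 times on another, too variable near background to decide. Neither explanation can be told apart from a LoVo culture with low epithelial expression, since no reference profile of the line was used here.

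For the counts, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 160 called genes and the highest other 0, with 1 split as large. At least 2-fold change held for 42 genes in the real split and 0 in the highest other, again 1 split as large. Gene lists called numbered 2 in the real split and 3 in the highest other, with 3 splits as large.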
